A study of Homo sapiens with 9 samples.

How the data were processed

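Polyadenylated RNA of U2OS osteosarcoma cells was sequenced in 9 libraries, 3 from cells given a non-silencing siRNA (siNS), 3 from cells given an siRNA against NFKB2 (siNFKB2) and 3 from cells given an siRNA against RELB (siRELB). Per the labels' protocols, the siRNA was used at 75 nM, RNA was taken 48 h after transfection with a lipid reagent and purified on columns, and libraries were made from oligo-dT selected RNA. Groups and replicate numbers were taken from the labels. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

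The authors deposited 1 table of whole-number read counts per gene for each library, with no normalization and with 44608 named entries per table. Trimmomatic 0.38, STAR 2.7.1a, Subread 1.6.4 and the genome build GRCh38.p13 are named in the submitters' processing notes, per the labels. The role and settings of each tool, the gene annotation and whether counting used the strand are not given in the sources used here. Genes are listed by symbol. Of the entries, 5005 carry a suffix for a further placement of 2652 genes, and these held at most 0.0369% of the counts of a library. They were kept apart in the main analysis and summed with the plain symbol in an alternative. Mitochondrial transcripts are represented by 22 tRNA and 2 rRNA entries, so the list of 13 mitochondrially encoded proteins was not analysed here. Total counts ranged from 15011789 to 19279572 per library. Within a group every pair of libraries differed by more than sampling noise, with chi-square values per degree of freedom between 3.31 and 83.5. No library was therefore a copy of another, and all 9 were counted as samples. These values cannot tell separate cultures from repeat preparations. The siRELB replicates 2 and 3 were the most alike, at 3.31, and every other pair was at 16.8 or more.

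All computation started from the deposited counts. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3, which left 14815 genes, and libraries were scaled by TMM. A single model with 3 group means was fitted to all 9 libraries, and each comparison was tested with edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05 with no minimum fold. Every adjusted p printed for a gene comes from this test unless another is named. The common biological coefficient of variation was 0.184 and the prior degrees of freedom were 4.35. Levels are in CPM, edgeR's unit of counts relative to library size, on TMM-scaled library sizes, as mean ± SD, n = 3. Some log2 fold changes carry a standard error (SE). It was derived from the test as the absolute log2 fold change divided by the square root of the F statistic. The comparisons were siNFKB2 against siNS, siRELB against siNS, siNFKB2 against siRELB, and any difference among the 3 groups.

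The design, the main alternatives and 26 gene lists were fixed before the data were examined. The lists cover homologous recombination, Fanconi anaemia, end joining, mismatch repair, base excision repair, nucleotide excision repair, the damage checkpoint, G1/S phase, G2/M phase, E2F and RB regulators, replication-dependent histones, p53 targets, the NF-kB pathway, NF-kB targets, the interferon response, the integrated stress response, the unfolded protein response, cholesterol synthesis, hypoxia and glycolysis, extracellular matrix, bone lineage, ribosomal proteins, mitochondrially encoded proteins, oxidative phosphorylation, epithelial markers and blood markers. The series title names lower expression of recombination genes after NFKB2 knockdown, so the direction for that list was known. For 25 lists in 3 comparisons, camera (limma 3.58.1) with its preset correlation of 0.01 compared the members with all other genes, and its p-values were adjusted together by Benjamini-Hochberg over 75 tests. Every list was also tested by camera with an estimated correlation and by fry. Members called are counted over all genes tested and, separately, adjusted over the list alone.

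Named genes follow a rule fixed beforehand. NFKB2 and RELB are named in every comparison. Among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups, the 10 largest rises and falls are named in each comparison with siNS, and the 5 largest each way between the knockdowns, among genes called the same way in both knockdowns, and among genes called in opposite directions. Up to 4 members of each list with the smallest adjusted p are named, and up to 12 for homologous recombination. Some genes that meet the rule are not reported here. Any gene named outside this rule is said to have been chosen after its values were seen. Overlaps between gene models were taken from GENCODE 29 on GRCh38, which may not be the annotation used for counting.

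Tested on simulated counts for siNFKB2 against siNS with 14467 genes, the analysis recovered 1.6% of 64 genes changed 1.5-fold, 46.3% of 67 genes changed 2-fold and 95.5% of 66 genes changed 4-fold, with 4 false calls among 99. A gene that was not called may therefore still differ by 2-fold or more. The simulation gave 99 calls, against 3869 in the data, and fewer changed genes make the adjusted threshold stricter. Recovery in the data may therefore be higher than these shares.

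Alternatives were RLE factors, upper quartile factors, total counts alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, only the 6 libraries compared, the replicate number as a block, a fold of at least 1.5, an adjusted p below 0.01, each library left out in turn, and removal of each library's trend on GC content and transcript length, alone and with the block. GC content and length were known for 91.3% of tested genes. After seeing the data 3 more were added, namely entries for further placements summed, the 3 libraries numbered 1 left out, and the log2 mitochondrial rRNA share as a covariate. The libraries numbered 1 lay apart on the second principal component, which held 24.7% of the variance. To ask whether replicate numbers pair libraries across groups, deviations from group means were correlated across genes. For siNFKB2 and siRELB the correlations were 0.54, 0.17 and 0.45 for numbers 1, 2 and 3, all above 0.1. The blocked count of calls and the calls gained with the block are therefore given beside that comparison. Its other values are from the fit without the block unless the block is named. The pairing rests on these correlations and on the numbers in the labels, which name no shared day or batch.

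Sequence matches of 7 bases in 3′ UTRs were examined for traces of siRNA seed effects. Log2 fold changes of 12412 genes with an annotated 3′ UTR of at least 50 bases were regressed on the presence of each possible 7-mer, after removing trends on UTR length, UTR GC content and mean level, with Bonferroni adjustment over all 7-mers. In 10 draws with fold changes shuffled among genes, a 7-mer planted at log2 -0.3 was found in all 10. Before planting, no false 7-mer passed in any draw. Shuffling removes any link between UTR sequence and genes that change together, so the draws cannot show false 7-mers from that source. The planted effect was also larger than the strongest links found, -0.223 in siNFKB2 and -0.143 in siRELB. The siRNA sequences are not given in the sources used here. Simulations of 9 unchanged libraries, 20 draws, gave the correlation that shared controls alone produce. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the plots.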

Results

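The series measured gene expression in U2OS cells, a human osteosarcoma line, after siRNA knockdown of NFKB2 or RELB. NFKB2 encodes a precursor that is processed to a DNA-binding NF-kB subunit, and RELB encodes the subunit it pairs with in the non-canonical NF-kB pathway. Read counts per gene were available for 3 siNS, 3 siNFKB2 and 3 siRELB libraries. Total counts were 18987115, 16330036 and 18428660 in siNS replicates 1 to 3. They were 18842542, 17898460 and 15011789 in siNFKB2 and 19279572, 18132699 and 17658315 in siRELB. Mitochondrial rRNA, which can mark differences in RNA quality or selection, took 0.406%, 1.33% and 0.63% of counts in siNS, 0.519%, 1.01% and 2.68% in siNFKB2, and 0.379%, 0.653% and 0.856% in siRELB. Levels are in CPM as mean ± SD, n = 3 libraries per group.

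The targets were measured first, because they check the labels. NFKB2 (chromosome 10, 102394110 to 102402529, plus strand, GRCh38, GENCODE 29) fell from 108.1 ± 24.2 CPM in siNS to 25.5 ± 21.7 CPM in siNFKB2, a log2 fold change of -2.09 (SE 0.564, adjusted p = 0.021). The remaining level was 4.87%, 21.1% and 44.8% of the siNS mean in siNFKB2 replicates 1 to 3, so depletion differed between these libraries. RELB (chromosome 19, 45001430 to 45038198, plus strand) fell from 27.2 ± 8.92 CPM to 4.23 ± 1.40 CPM in siRELB, a log2 fold change of -2.69 (SE 0.369, adjusted p = 0.00881). Its remaining level was 9.79%, 17.1% and 19.7% of the siNS mean. RELB was at 35.3 ± 12.3 CPM in siNFKB2 (adjusted p = 0.447), and NFKB2 was at 151.5 ± 29.5 CPM in siRELB (adjusted p = 0.695). The NFKB2 call was lost with 3 libraries left out singly, at an adjusted p of 0.0532 without siNS replicate 2, 0.0667 without siNS replicate 3 and 0.0936 without siNFKB2 replicate 2, and with only the 6 libraries compared (0.0502). The RELB call was lost without siNS replicate 3 (0.0575) and without siRELB replicate 2 (0.0591). Over the 22 alternatives the adjusted p ranged from 6.71e-05 to 0.0936 for NFKB2 and from 1.72e-11 to 0.0591 for RELB, and every fold change stayed negative.

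**Figure D1:**
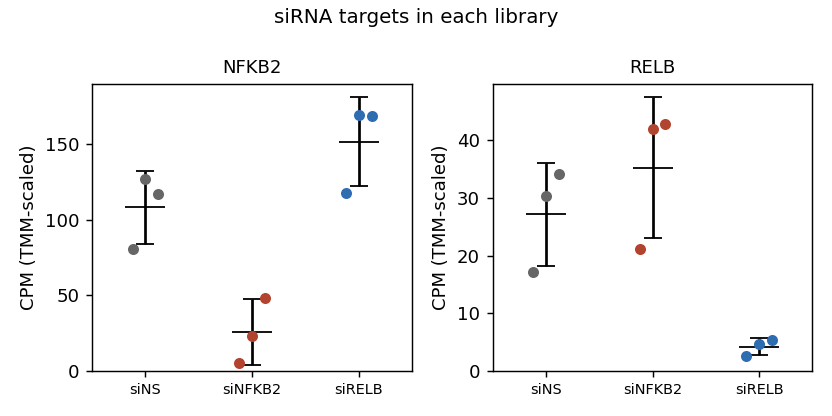
Level of NFKB2 and RELB in CPM (vertical axis, TMM-scaled) in each library of the 3 groups (horizontal axis), with points for libraries, a horizontal line for the group mean and bars for the SD. NFKB2 is lowest in the siNFKB2 libraries, at 5.26, 22.9 and 48.4 CPM, and RELB is lowest in the siRELB libraries, at 2.66, 4.66 and 5.36 CPM.

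The comparison of siNFKB2 with siNS asked which genes change when NFKB2 is depleted, and the series title puts genes of homologous recombination in its centre. Of 52 recombination genes tested, 25 fell and 2 rose, or 28 and 2 when adjusted over the list alone, and the median log2 fold change was -0.52. The list was lower than other genes by camera (adjusted p = 4.39e-07), though with an estimated correlation the adjusted p = 0.293. Relative to the siNS mean, the list's median was -0.30, -0.61 and -0.63 in siNFKB2 replicates 1 to 3. It thus changed least in replicate 1, the library with the least NFKB2 left (4.87% of the siNS mean). However, deviations of siNFKB2 and siNS replicates 1 correlated at 0.58, and the list's median was -0.37 without siNS replicate 1. A mean over all siNS libraries may therefore understate the fall in replicate 1, and no relation to depletion can be read from this order. BLM, a helicase that processes recombination intermediates, fell from 50.1 ± 0.778 to 23.7 ± 3.89 CPM (log2 -1.08, adjusted p = 0.000564), and RMI2, a member of its complex, from 23.5 ± 2.57 to 11.9 ± 0.261 CPM (log2 -0.98, adjusted p = 0.00139). Further named members were TONSL (log2 -1.23), BRIP1 (-0.90), RAD54L (-0.89), SFR1 (-0.78), RAD54B (-0.77), MCM8 (-0.76), RAD51D (-0.74), POLD2 (-0.74) and RPA3 (-0.74), with adjusted p from 0.00159 to 0.00425. The 2 members that rose were NBN (log2 0.47) and HELQ (0.42), named after their values were seen. TONSL has further placements in the tables, RAD54B shares 63.3% of its exonic length with FSBP on the same strand, and RAD54L shares 18.0% with LRRC41 on the opposite strand, so these counts are uncertain. BLM, MCM8, RAD51D and POLD2 carry in their 3′ UTR a 7-mer that was linked to lower values in siNFKB2, as do 37.8% of all genes searched. Of searched genes called lower 48.8% carry one, and of those called higher 33.4%.

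**Figure D2:**
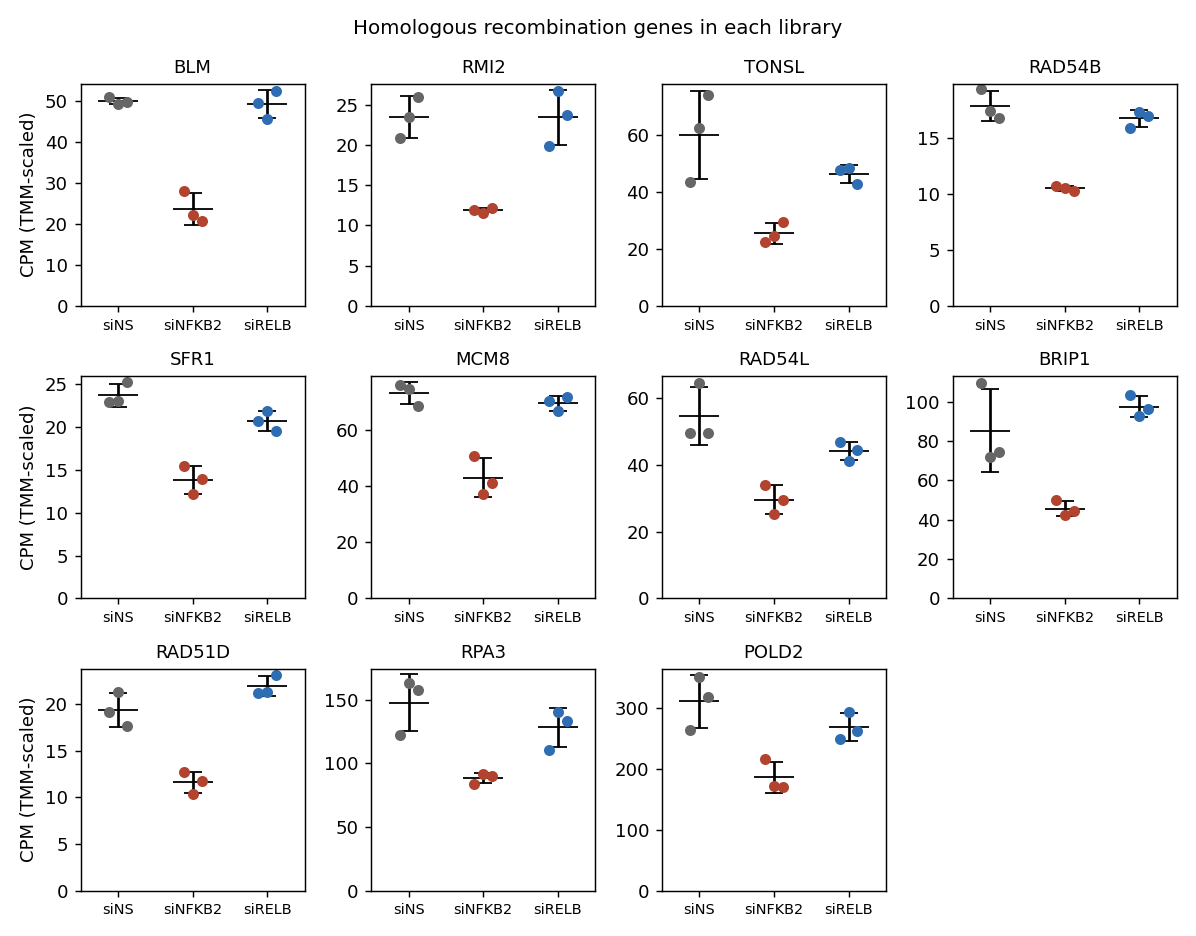
Level in CPM (vertical axes, TMM-scaled) of 11 named recombination genes in each library of the 3 groups (horizontal axes), with points for libraries, a horizontal line for the mean and bars for the SD. BLM has group means of 50.1 CPM in siNS, 23.7 CPM in siNFKB2 and 49.3 CPM in siRELB.

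Lists of cell cycle genes were lower too, and differences between lists were not tested. Of 41 genes of G1/S phase, when DNA replication is prepared, 37 fell (39 adjusted over the list alone). The median was -0.91 (camera adjusted p = 3.12e-25, and adjusted p = 0.293 with an estimated correlation), and relative to the siNS mean it was -0.63, -1.02 and -1.09 in siNFKB2 replicates 1 to 3. UHRF1 (log2 -1.46), CDC45 (-1.10) and PCNA (-1.09), which serve DNA replication and its chromatin, were among them. Among 54 genes of G2/M phase, 37 fell (39 adjusted over the list alone, with 1 higher), with a median of -0.69 (adjusted p = 5.1e-14, and adjusted p = 0.293 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell from 373.9 ± 44.9 to 132.2 ± 27.6 CPM (log2 -1.50, SE 0.158, adjusted p = 0.00029), beside PIMREG (-1.23), TUBB4B (-1.02) and KIF2C (-0.80). Of 33 E2F and RB regulators, 14 fell and 4 rose (15 and 5 adjusted over the list alone), with a median of -0.34 (adjusted p = 0.00804, and adjusted p = 0.443 with an estimated correlation), or -0.21 without siNS replicate 1 (adjusted p = 0.0686). E2F1 (log2 -1.41), CCNE1 (-1.16) and CDKN2C (-1.54) fell, whereas CCND2 (0.97) rose, as did E2F3 (0.97), CCND1 (0.56) and CDKN1A (0.52), which were named after their values were seen. CDKN2C and CDKN1A encode inhibitors of cyclin-dependent kinases. Of the 52 recombination genes, 45 are on none of these cell cycle lists, and 19 of the 45 fell, with a median of -0.43 (unadjusted camera p = 1.88e-05, or 0.0414 with an estimated correlation).

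Other repair lists were lower as well, but they share members with each other and with the cell cycle lists. On a cell cycle list were 1 of 24 Fanconi anaemia, 3 of 10 mismatch repair, 2 of 22 base excision repair and 3 of 20 checkpoint genes. These lists were not tested without those members. In the Fanconi anaemia list, which acts on DNA crosslinks, 11 of 24 genes fell and 2 rose (12 and 3 adjusted over the list alone, median -0.39, adjusted p = 0.0151), led by FANCG (log2 -1.10), UBE2T (-0.83) and FANCE (-0.82). WDR48 (0.66) and REV3L (0.62, named after its value was seen) rose. In mismatch repair, 5 of 10 fell (5 adjusted over the list alone, median -0.45, adjusted p = 0.00171). Among them were LIG1 (log2 -1.47), PCNA (-1.09), MSH6 (-0.90) and EXO1 (-0.97, named after its value was seen), and MSH6 overlaps FBXO11 on the opposite strand over 21% of its exonic length. In base excision repair, 10 of 22 fell and 2 rose (11 and 2 adjusted over the list alone, median -0.44, adjusted p = 0.00288), with LIG1, FEN1 (-1.03) and UNG (-0.67) lower and PARP3 (0.97) and TDG (0.42, named after its value was seen) higher. Damage checkpoint genes fell in 7 of 20 cases (8 adjusted over the list alone, median -0.30, adjusted p = 0.0214), among them CDC25C (-1.17), TIMELESS (-1.12), CDC25B (-0.78) and TIPIN (-0.74), and CDC25C shares 10.7% of its exonic length with FAM53C on the opposite strand. With an estimated correlation the adjusted p were 0.293 for Fanconi anaemia, 0.397 for mismatch repair, 0.404 for base excision repair and 0.368 for the checkpoint. The checkpoint median was -0.14 without siNS replicate 1 (adjusted p = 0.0517) and -0.18 without siNFKB2 replicate 2, where the list kept its call.

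Genes induced by NF-kB rose. Of 29 NF-kB targets tested, 21 rose and 1 fell (24 and 2 adjusted over the list alone), with a median of 1.39 (adjusted p = 3.15e-13, and adjusted p = 0.293 with an estimated correlation). The gene that fell was IL11 (log2 -0.87), named after its value was seen. BCL2A1, an anti-apoptotic protein, rose from 1.34 ± 0.441 to 46.0 ± 28.9 CPM (log2 5.09, SE 0.625, adjusted p = 0.000504). The cytokine IL24 rose from 2.65 ± 0.532 to 51.7 ± 4.35 CPM (log2 4.28, SE 0.174, adjusted p = 2.31e-06), and the chemokine CXCL8 from 6.07 ± 1.18 to 91.9 ± 44.1 CPM (log2 3.92, SE 0.475, adjusted p = 0.000475). The matrix metalloproteinases MMP1 (log2 3.86) and MMP3 (2.33), the cytokine IL1A (2.92) and TNFAIP2 (2.02) rose too. In the NF-kB pathway list 9 of 25 genes rose and 1, TRAF2 (log2 -0.57, named after its value was seen), fell (12 and 1 adjusted over the list alone, median 0.43, adjusted p = 0.000669, and adjusted p = 0.45 with an estimated correlation). Those with the smallest adjusted p were CYLD (log2 1.47), BIRC3 (3.11), TRAF1 (3.80) and NFKBIE (1.61), and CYLD and NFKBIE encode restraints of NF-kB signalling. The pathway list and the target list each have 5 tested members that are also on another list, so their results may not be separate. The medians of the NF-kB targets in siNFKB2 replicates 1 to 3, relative to the siNS mean, were 0.72, 1.85 and 1.63, again least in replicate 1. This order has the same limit, as deviations that replicates 1 share were not removed.

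The lists of cholesterol synthesis, replication-dependent histones, and hypoxia and glycolysis were higher than other genes by camera, although most members of the histone and hypoxia lists were not called. Of 22 genes of cholesterol synthesis, 15 rose and 1, PMVK (log2 -0.63, named after its value was seen), fell (16 and 2 adjusted over the list alone, median 0.61, adjusted p = 8.79e-09, and adjusted p = 0.293 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 477.3 ± 78.5 to 1680 ± 331.3 CPM (log2 1.82, SE 0.165, adjusted p = 0.000253), with MSMO1 (1.55), SQLE (1.51) and DHCR7 (1.13). Of 16 replication-dependent histone genes, 5 rose (5 adjusted over the list alone, median 0.36, adjusted p = 0.00665, and adjusted p = 0.293 with an estimated correlation). These were HIST1H4H (log2 1.62), HIST2H2BE (1.48), HIST1H2BC (1.33), HIST1H2BK (1.11) and HIST1H2BG (1.57, named after its value was seen). Histone genes are near-identical copies whose main transcripts lack poly(A) tails, so their counts are uncertain. In the hypoxia and glycolysis list 10 of 28 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.22, adjusted p = 0.0214, and adjusted p = 0.617 with an estimated correlation), with ALDOC (log2 1.98), SLC2A3 (0.68) and PDK1 (0.67) higher and NDRG1 (-2.10) and PFKP (-0.45, named after its value was seen) lower. Without siNS replicate 1 the adjusted p of the histone and hypoxia lists were 0.051 and 0.0603, and without siNFKB2 replicate 2 that of the hypoxia list was 0.0867. Without the 3 libraries numbered 1 the histone and hypoxia lists were at 0.063 and 0.0527, a setting chosen after seeing the data. The histone median ranged from 0.16 with no filter to 1.21 at a mean of at least 5 CPM, so its size depended on which genes were kept.

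In all, 3869 of 14815 genes were called between siNFKB2 and siNS, of which 1872 were higher and 1997 lower. Besides those above, the largest rises were PRR9 (log2 5.03), the interleukin receptor IL1RL1 (4.43), the chemokine CCL20 (4.02), the growth factor CSF2 (3.49) and G0S2 (3.27), with adjusted p from 5.31e-05 to 0.00281. Among the largest falls were the matrix glycoprotein EFEMP1, from 130 ± 4.37 to 14.4 ± 7.29 CPM (log2 -3.16, SE 0.277, adjusted p = 0.000248), TXNIP (-3.14), ID4 (-2.81), ALDH3B1 (-2.56), ITGB3 (-2.53), UBBP4 (-2.50), the fatty acid oxidation enzyme HADHA (-2.42), AKR1A1 (-2.37) and BLMH (-2.35). UBBP4 is a ubiquitin pseudogene whose reads may belong to its near copies. EFEMP1, TXNIP, ALDH3B1, ITGB3, HADHA and BLMH carry in their 3′ UTR a 7-mer linked to lower values in siNFKB2, as do 37.8% of all genes searched and, among the rises, PRR9, IL1RL1 and CXCL8. Such a 7-mer is carried by 48.8% of searched genes called lower and 33.4% of those called higher. The count of calls fell to 2220 without siNFKB2 replicate 2 and to 2352 without siNS replicate 3, and rose to 6711 without the 3 libraries numbered 1, a setting chosen after seeing the data. Of 131 named gene values called here, between 115 and 130 kept their call with 1 library left out. The damage checkpoint, E2F and RB, histone and hypoxia lists lost their calls without siNS replicate 1 (adjusted p = 0.0517, 0.0686, 0.051 and 0.0603), and the hypoxia list without siNFKB2 replicate 2 (0.0867), within ranges of 0.0124 to 0.0517, 0.000331 to 0.0686, 0.00219 to 0.051 and 0.0117 to 0.0867 over the 9 libraries left out.

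For 12 lists the camera adjusted p was 0.05 or more in siNFKB2. These were end joining (5 lower and 1 higher of 19, median -0.16, adjusted p = 0.205), nucleotide excision repair (2 and 2 of 20, 0.13, 0.758), p53 targets (1 and 7 of 27, 0.29, 0.112), the interferon response (3 and 2 of 27, -0.22, 0.515), the integrated stress response (1 and 4 of 27, 0.14, 0.382) and the unfolded protein response (4 and 3 of 22, -0.17, 0.773). In the same order of values they were also extracellular matrix (9 and 5 of 31, -0.03, 0.333), bone lineage (4 and 4 of 12, -0.06, 0.974), ribosomal proteins (4 lower of 38, -0.13, 0.208), oxidative phosphorylation (4 lower of 27, -0.13, 0.23), epithelial markers (2 and 1 of 6, 0.18, 0.703) and blood markers (2 lower of 6, -0.33, 0.617). Some of these passed camera under alternatives. The p53 targets passed with the replicate block (adjusted p = 0.0248), the GC and length trend removed (0.0239), both together (0.0121), no filter (0.0331), without siNFKB2 replicate 1 (0.0428) and without the 3 libraries numbered 1 (0.0252), in a range of 0.0121 to 0.508. End joining passed with no filter (0.046, range 0.046 to 0.414) and the integrated stress response with the trend removed and the block (0.043, range 0.043 to 0.813). Ribosomal proteins passed without siNS replicate 1 (0.00469), without the 3 libraries numbered 1 (0.0304) and with the mitochondrial covariate (0.0232), in a range of 0.00469 to 0.957. By fry, which does not compare a list with other genes, p53 targets (0.0212) and end joining (0.00251) also passed. Single members changed all the same. XRCC5 (log2 -0.97) and MAD2L2 (-0.65) of end joining fell and SHLD2 (0.70) rose, the damage sensor XPC (-0.84) fell, and the collagen gene COL5A1 (-2.15), TGFB2 (-1.33), FN1 (-1.11) and THBS1 (-0.79) fell. The bone regulator RUNX2 (-1.36) and BMP4 (-1.20) fell, whereas BMP2 (1.05) and PHEX (1.83) rose. For bone lineage and epithelial markers the median and the camera test differed in sign.

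The comparison of siRELB with siNS asked the same of RELB. Far fewer genes were called, 299 of 14815 (2.02%), with 179 higher and 120 lower, and recombination genes were not among them. At that share few calls would be likely in any list of 52 genes, so their absence alone says little about recombination genes. NPPB, which encodes a natriuretic peptide, rose from 3.19 ± 1.62 to 24.1 ± 10.2 CPM (log2 2.93, SE 0.44, adjusted p = 0.0122), and OLR1, a receptor for oxidised lipoprotein, from 8.65 ± 2.42 to 56.5 ± 2.08 CPM (log2 2.7, SE 0.314, adjusted p = 0.00516). CNDP2, a dipeptidase, fell from 284.8 ± 14.97 to 66.2 ± 11.6 CPM (log2 -2.10, SE 0.138, adjusted p = 3e-04), and the collagen receptor subunit ITGA2 from 104.5 ± 20.3 to 19.9 ± 11.6 CPM (log2 -2.39, SE 0.35, adjusted p = 0.0114). The other largest rises were MOB3B (log2 2.30), CXCL8 (2.27), GBP1 (1.93), TNFRSF9 (1.91), TMEM255A (1.91), PRR9 (1.89), DCLK1 (1.67) and DSP (1.66), with adjusted p from 0.00236 to 0.0388. Further large falls were SCML1 (-2.12), ADM (-1.77), TXNIP (-1.76), IL17RD (-1.71), UBBP4 (-1.61), PGAP2 (-1.51), YBX3 (-1.49) and UBE2F (-1.47), with adjusted p from 0.00221 to 0.0188. CNDP2, ITGA2, SCML1, IL17RD, PGAP2, YBX3 and UBE2F carry in their 3′ UTR a 7-mer linked to lower values in siRELB, as do 27.8% of all genes searched and, among the rises, OLR1, TMEM255A and DCLK1. Such a 7-mer is carried by 59.4% of searched genes called lower in siRELB and 20.6% of those called higher. UBE2F overlaps UBE2F-SCLY on the same strand over 23.2% of its exonic length.

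In siRELB 0 of 52 recombination genes were called by edgeR's quasi-likelihood test, also when adjusted over the list alone, and 0 by DESeq2, with 3 higher and 2 lower at an unadjusted p below 0.05. Their median was -0.02 (camera adjusted p = 0.773). BLM was at 49.3 ± 3.42 CPM in siRELB beside 50.1 ± 0.778 CPM in siNS. Camera called 6 lists. Ribosomal proteins were lower with a median of -0.33 over 38 genes (adjusted p = 2.73e-09, and adjusted p = 0.508 with an estimated correlation), although RPL5 (log2 -0.47, adjusted p = 0.0393) was the single member called (3 lower adjusted over the list alone). Oxidative phosphorylation (27 genes, median -0.17, adjusted p = 0.0063), base excision repair (22 genes, -0.14, 0.00959), hypoxia and glycolysis (28 genes, -0.23, 0.0137) and G1/S phase (41 genes, -0.12, 0.0151) were lower. ADM of the hypoxia list was the only member of these 4 lists called by edgeR's quasi-likelihood test, while 4, 5, 9 and 5 members were lower at an unadjusted p below 0.05 and DESeq2 called 1, 2, 3 and 2 lower. Cholesterol synthesis was higher (22 genes, median 0.20, adjusted p = 0.00804), with 0 members called by edgeR's quasi-likelihood test, 5 higher adjusted over the list alone, 8 at an unadjusted p below 0.05 and 4 by DESeq2. HMGCS1 was at 744.9 ± 36.8 CPM against 477.3 ± 78.5 CPM (adjusted p = 0.0786). With an estimated correlation the adjusted p were 0.675 for oxidative phosphorylation, 0.443 for base excision repair, 0.577 for hypoxia, 0.743 for G1/S phase and 0.53 for cholesterol synthesis. NF-kB targets had a median of 0.24 and 1 of 29 called, CXCL8 (camera adjusted p = 0.144). That list passed camera as higher in 6 alternatives, with only the 6 libraries compared (0.0209), without siNS replicate 3 (0.0328), siNFKB2 replicate 1 (0.0426) or siRELB replicate 1 (0.0196), with the GC and length trend removed and the block (0.016) and without the 3 libraries numbered 1 (0.014), in a range of 0.014 to 0.789. The interferon response passed camera as higher at a mean of at least 5 CPM (0.0199, range 0.0199 to 0.789). The integrated stress response passed as higher with the trend removed and the block (0.0213, range 0.0213 to 0.726). E2F and RB regulators passed as lower without siNS replicate 2 (0.0128, range 0.0128 to 0.928). FN1 (-0.51), THBS1 (-0.62) and TNC (-0.59) of the extracellular matrix fell and COL12A1 (0.46) rose, and the mitotic kinase AURKA (-0.81) and E2F5 (-1.09) fell.

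The siRELB calls depended on single libraries. Their number was 1819 without siNS replicate 1, 60 without siNS replicate 2, 19 without siNS replicate 3, 150 and 177 without siNFKB2 replicates 2 and 3, and 184, 15 and 30 without siRELB replicates 1, 2 and 3. It was 3390 without the 3 libraries numbered 1, a setting chosen after seeing the data. Of 35 named gene values called in siRELB, 35, 21 and 8 kept their call without siNS replicates 1, 2 and 3, 35, 27 and 29 without siNFKB2 replicates 1, 2 and 3, and 26, 8 and 13 without siRELB replicates 1, 2 and 3. CNDP2, MOB3B, SCML1, PGAP2, YBX3 and DSP kept theirs with each library left out, and NPPB lost its call without siNS replicate 3 (adjusted p = 0.103), siRELB replicate 2 (0.0707) and siRELB replicate 3 (0.0697). Base excision repair, G1/S phase, hypoxia and oxidative phosphorylation each lost their call without at least 1 library, at an adjusted p of up to 0.061, 0.254, 0.0603 and 0.0581, while ribosomal proteins and cholesterol synthesis kept theirs with each of the 9 left out. Medians moved too, to -0.24 and -0.08 for base excision repair and -0.04 and -0.19 for G1/S phase without siNS replicates 1 and 2, -0.11 for oxidative phosphorylation without siRELB replicate 1 and -0.15 for hypoxia without siRELB replicate 3.

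The direct comparison of siNFKB2 with siRELB tested whether the knockdowns differed. BLM was lower in siNFKB2 than in siRELB, at 23.7 ± 3.89 against 49.3 ± 3.42 CPM (log2 -1.05, SE 0.136, adjusted p = 0.000622). Of 52 recombination genes 25 were lower and 1, HELQ (log2 0.40, named after its value was seen), was higher (26 and 3 adjusted over the list alone, median -0.52, camera adjusted p = 1.75e-06, and adjusted p = 0.293 with an estimated correlation). BABAM2 (-1.10), BRIP1 (-1.09), FIGNL1 (-1.07), EXO1 (-1.07), DNA2 (-1.02), RMI2 (-0.98), RAD51D (-0.91), C1orf112 (-0.80), MCM8 (-0.69) and RAD54B (-0.67) were further named members. G1/S genes were lower in 34 of 41 cases (37 adjusted over the list alone, median -0.75, adjusted p = 4.08e-18), G2/M genes in 35 of 54 (39, -0.62, 1.15e-11) and mismatch repair genes in 5 of 10 (5, -0.37, 0.00881), the last including LIG1, PCNA, EXO1 and MSH6. NF-kB targets were higher in 19 of 29 cases (20 adjusted over the list alone, median 1.23, adjusted p = 4.91e-10), cholesterol synthesis in 13 of 22 (16, 0.48, 9.87e-05), hypoxia and glycolysis in 16 of 28 (18, 0.48, 9.87e-05), histones in 6 of 16 (7, 0.60, 0.00319), the NF-kB pathway in 7 of 25 (7, 0.23, 0.00839) and p53 targets in 8 of 27 (9, 0.26, 0.0287). Called members went the other way in 6 of these lists, namely CKS1B (log2 0.61) of G2/M, MLH3 (0.37) of mismatch repair, IL11 (-1.34) and CSF1 (-0.65) of the NF-kB targets, EBP (-0.60) of cholesterol synthesis, NDRG1 (-2.19) of hypoxia and XPC (-0.78) of the p53 targets. CKS1B, MLH3, IL11, CSF1 and EBP were named after their values were seen. CDKN1A (log2 0.81), TRIAP1 (0.68) and GADD45A (1.06) were among the higher p53 targets. The NF-kB pathway list lost its call with the mitochondrial rRNA share as a covariate (0.0541, range 1.21e-06 to 0.577), a setting chosen after seeing the data, and by fry (0.055). With an estimated correlation the adjusted p were 0.293 for G1/S and G2/M genes and histones, 0.387 for NF-kB targets, 0.577 for the pathway, and 0.404 for mismatch repair, cholesterol synthesis, hypoxia and p53 targets.

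Between the knockdowns 3934 genes were called, 1813 higher and 2121 lower in siNFKB2. With the replicate number as a block the count was 6054, of which 51.16% were lower in siNFKB2. The median of the recombination list was -0.52 with the block. BCL2A1 (log2 4.64), G0S2 (4.39), CSF2 (3.89), CCL20 (3.78) and ITGA2 (3.42) were highest in siNFKB2 relative to siRELB, and NPPB (-5.03), the cardiac troponin gene TNNT2 (-3.16), PDLIM1 (-3.16), and EFEMP1 (-2.96) among the lowest. With the block 2 more lists passed camera, E2F and RB regulators (median -0.28, adjusted p = 0.0378) and ribosomal proteins (0.23, 0.0237), in ranges of 0.00913 to 0.642 and 0.0149 to 0.816. With an estimated correlation and no block their adjusted p were 0.642 and 0.816, and the block was not run with an estimated correlation. Fanconi anaemia, base excision repair and the damage checkpoint were not called here (camera adjusted p = 0.145, 0.183 and 0.0889). With no filter they passed camera as lower (0.0385, 0.043 and 0.0135). The checkpoint also passed without siNFKB2 replicate 1 (0.0497) and without the 3 libraries numbered 1 (0.0453). With an estimated correlation these lists were at 0.404, 0.726 and 0.404. By fry, Fanconi anaemia (adjusted p = 0.000333), the checkpoint (0.00535) and E2F and RB regulators (0.0489) were lower, but base excision repair was not called (0.0569). End joining was lower by fry (adjusted p = 0.0159) and not called by camera (0.486). The named genes RPL4, SDHB, NDUFB8 and SDHA were called with the block. The count of calls fell to 2188 and 2593 without siNFKB2 replicates 2 and 3 and to 2312 and 2340 without siRELB replicates 2 and 3, and it rose to 6600 without the 3 libraries numbered 1. Lower recombination genes numbered 14, 16 and 15 without siNFKB2 replicate 2, siRELB replicate 2 and siRELB replicate 3, and the p53 list lost its call without siNFKB2 replicate 2 (adjusted p = 0.0596) and siRELB replicate 1 (0.0673), in a range of 0.0131 to 0.0673. Over all 3 groups together 4443 genes differed, or 2385 and 2789 without siNFKB2 replicates 2 and 3.

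**Figure D3:**
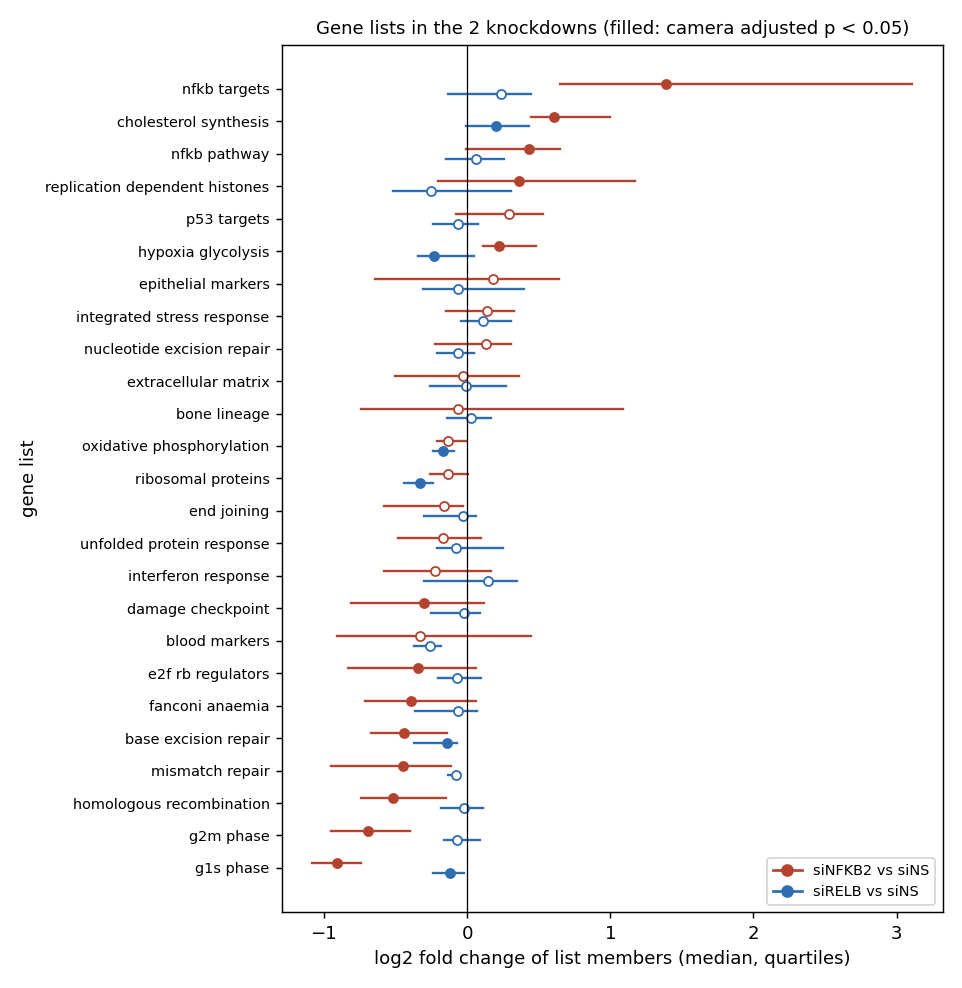
Median log2 fold change of the members of 25 gene lists (horizontal axis) against siNS, one list per line (vertical axis), in siNFKB2 and siRELB, with lines from the lower to the upper quartile and filled points where camera with its preset correlation gave an adjusted p below 0.05. In siNFKB2 NF-kB targets have the highest median, 1.39, and G1/S genes the lowest, -0.91, whereas the siRELB medians lie between -0.33 and 0.24.

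Some genes were called in both knockdowns. There were 93 higher in both and 37 lower in both, where independent lists of these sizes would share 22.6 and 16.2, and 29 were called in opposite directions. OLR1 (log2 2.83 in siNFKB2 and 2.7 in siRELB), CXCL8 (3.92 and 2.27), PRR9 (5.03 and 1.89), DCLK1 (2.00 and 1.67) and TNFRSF9 (1.56 and 1.91) rose most in both. TXNIP (-3.14 and -1.76), UBBP4 (-2.50 and -1.61), the activin antagonist FST (-1.58 and -1.34), ITGB8 (-1.58 and -1.27) and CCDC144NL-AS1 (-1.45 and -1.25) fell most in both, and the last is an antisense gene whose strand could not be told apart from its neighbours. NPPB (-2.10 and 2.93), PDLIM1 (-1.66 and 1.504), TNNT2 (-1.86 and 1.304), IL17RD (1.11 and -1.71) and ITGA2 (1.04 and -2.39) went opposite ways. In siNFKB2 the NPPB call was lost without siNS replicate 2 (adjusted p = 0.0599), siNFKB2 replicate 1 (0.0538) and siNFKB2 replicate 2 (0.0521), and the ITGA2 call without siNS replicates 2 and 3 (0.121 and 0.118) and siNFKB2 replicates 2 and 3 (0.152 and 0.101). In siRELB all 5 lost their call without siNS replicate 3, siRELB replicate 2 and siRELB replicate 3, at adjusted p of 0.103, 0.0707 and 0.0697 for NPPB, 0.0691, 0.0591 and 0.0651 for PDLIM1, 0.152, 0.138 and 0.141 for TNNT2, 0.0515, 0.0593 and 0.0585 for IL17RD, and 0.0687, 0.0664 and 0.0697 for ITGA2. Of the genes named as changed the same way in both, each but CCDC144NL-AS1 lost its siRELB call without at least 1 library, from OLR1 without siNS replicate 3 (0.0506) to ITGB8 without siRELB replicate 3 (0.216). Both comparisons use the same 3 siNS libraries. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.276, where simulated unchanged groups gave a mean of 0.498. Their covariance was 0.0782 against a simulated 0.0419. The simulation holds shared controls alone, not the deviations that same-numbered siNFKB2 and siRELB libraries share (correlations of 0.54, 0.17 and 0.45), which would also raise the covariance. No analysis with separate controls was run, so part of the overlap may come from either. Shared calls numbered 130, and 1012, 21 and 5 without siNS replicates 1, 2 and 3, 64 and 68 without siNFKB2 replicates 2 and 3, and 72, 6 and 15 without siRELB replicates 1, 2 and 3.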

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

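3 of the alternatives were chosen after seeing the data, namely summing further placements, leaving out the 3 libraries numbered 1, and the mitochondrial rRNA share as a covariate. No called value of a named gene and no median of a called list changed sign under the alternatives run. Medians of lists that were not called did, such as histones in siRELB (0.45 at a mean of at least 5 CPM), and in siNFKB2 ribosomal proteins (0.05 without siNS replicate 2) and blood markers (0.12 with only the 6 libraries compared). The share of siRELB calls that were lower ranged from 31.82% with total counts alone to 68.42% without siNS replicate 3. The recombination list stayed lower in siNFKB2 against siNS with 18 to 35 members lower. RLE, upper quartile and total-count scaling, the 5 CPM filter, no filter, a fold of at least 1.5 and summed placements left every count of calls within 1.5 times its value in the report. The number of calls in siNFKB2 against siNS was 5944 with the replicate block, 1937 at an adjusted p below 0.01, 6474 with the GC and length trend removed and the block, 6711 without the 3 libraries numbered 1 and 5988 with the mitochondrial covariate. In siRELB against siNS it was 813 with DESeq2, 129 with only the 6 libraries compared, 1570 with the replicate block, 48 at an adjusted p below 0.01, 738 with the GC and length trend removed, 2037 with that and the block, 3390 without the libraries numbered 1 and 1326 with the covariate. Between the knockdowns it was 6054 with the replicate block, 1877 at an adjusted p below 0.01, 6842 with the trend removed and the block and 6600 without the libraries numbered 1, and 14 recombination genes were lower at an adjusted p below 0.01. For any difference among the 3 groups it was 7247 with the block, 7996 with the trend removed and the block and 8310 without the libraries numbered 1. Shared calls numbered 330 with DESeq2, 63 with only the 6 libraries compared, 662 with the block, 15 at an adjusted p below 0.01, 317 with the trend removed, 858 with that and the block, 1678 without the libraries numbered 1 and 605 with the covariate. The NFKB2 knockdown was -2.09 at an adjusted p of 0.0502 with only the 6 libraries compared, within 6.71e-05 to 0.0936 over its alternatives. Camera with an estimated correlation called 0, 0 and 0 lists in siNFKB2, siRELB and the direct comparison, with 7, 0 and 4 at an unadjusted p below 0.05 and a smallest adjusted p of 0.293, 0.404 and 0.293, and fry called 15, 2 and 13. The 2 that fry called in siRELB were Fanconi anaemia (0.00515) and blood markers (0.0437). The 6 that camera called there had fry adjusted p from 0.0674 to 0.351, and 1 of them, base excision repair, an unadjusted p below 0.05 (0.0315). A stricter threshold calls fewer genes by construction, and for the other changes the cause was not tested.

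With each of the 9 libraries left out in turn, calls ranged from 2220 to 4895 in siNFKB2 against siNS, from 15 to 1819 in siRELB against siNS, from 2188 to 4917 between the knockdowns and from 2385 to 6472 among the 3 groups, and shared calls from 5 to 1012. The NFKB2 knockdown ranged from -2.93 to -1.60 and the RELB knockdown from -2.93 to -2.44, recombination genes lower between the knockdowns from 14 to 29, and lists called from 10 to 14, 4 to 7 and 9 to 12 in the 3 comparisons, and the cause was not tested. Of 272 called values of named genes, 225 to 271 kept their call in these settings, 249 of 271 with only the 6 libraries compared, 263 without a filter and 272 with DESeq2, which gave 2 further named values no adjusted p. Whether replicate numbers pair siNFKB2 or siRELB with siNS stays unclear. Deviations of same-numbered libraries correlated at 0.58, 0.05 and 0.09 for siNFKB2 and at 0.59, 0.38 and 0.04 for siRELB, and 5 of 9 libraries correlated best with their own number. Beyond the counts, lists and genes given here and in the report, the replicate block ended no call of a named gene or list. In the simulation, with 99 calls against 3869 in the data, 1.6% of 1.5-fold changes were recovered. Fewer changed genes make the adjusted threshold stricter, so this share may be higher in the data. Depth, spread and the number of libraries may also limit it, and which of these sets the limit was not tested.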

Other observations

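The test on the 7-mer ATTACAA and the tests on all 9 passing 7-mers of NFKB2 transcripts and on splits by replicate number were chosen after the result was seen. So was the use of the G1/S list below to withhold an exclusion. Beforehand a G1/S fall at least as far had been set only as part of what would favour that explanation. The other tests were fixed before, except that no bound was set beforehand for the permutation test of 7-mer carriers. The unfolded protein, integrated stress and interferon lists were not called in siNFKB2 (camera adjusted p = 0.773, 0.382 and 0.515), and their called members went both ways. In the unfolded protein response, the sensor ERN1 rose from 10.7 ± 1.44 to 27.4 ± 3.80 CPM (log2 1.36, SE 0.156, adjusted p = 0.000398) and EDEM1, which routes misfolded proteins to degradation, rose too (1.18), as did HERPUD1 (0.50), while the folding enzymes PDIA3 (-0.69), PDIA4 (-0.67) and PDIA6 (-0.51) and the transcription factor XBP1 (-0.84) fell. In the integrated stress response, SLC7A11 (1.96), DDIT4 (1.40), VLDLR (0.78) and TRIB3 (0.71) rose and NUPR1 (-1.06) fell. In the interferon response, ISG20 (1.12) and the RNA sensor DDX58 (0.69) rose and IFIT1 (-1.71), DDX60 (-1.03) and IFI44 (-0.90) fell. HERPUD1, PDIA3, XBP1, DDIT4 and IFIT1 were named after their values were seen. Calls were lost for NUPR1 without siNS replicates 2 and 3 (adjusted p = 0.0854 and 0.0773) and siNFKB2 replicates 2 and 3 (0.107 and 0.0818), for SLC7A11 without siNS replicate 3 (0.0648), for ISG20 without siNFKB2 replicate 2 (0.0516) and for IFI44 without siNFKB2 replicate 3 (0.0566). PDIA6 overlaps ATP6V1C2 on the opposite strand over 29.7% of its exonic length.

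The lower recombination list in siNFKB2 was weighed against 4 explanations. Of 9 7-mers linked to lower values and found in NFKB2 transcripts, 4 were stronger than any linked to higher values, and the 36 members without these 4 in the 3′ UTR stayed lower (median -0.38, unadjusted p = 4.36e-06 by limma's camera with its preset correlation and 0.0151 with an estimated one), as did the 26 without any of the 9 (median -0.38, unadjusted p = 6.58e-05 and 0.0193), which argues against direct seed matches as the whole cause, and the list stayed lower with the GC and length trend removed (unadjusted p = 5.86e-11) and without siNFKB2 replicate 3, the library with the most mitochondrial rRNA (unadjusted p = 2.32e-07). A general fall of S phase and mitotic transcripts stays open and cannot be told apart from a change of recombination genes in particular. The 45 members on no cell cycle list were lower too (unadjusted p = 1.88e-05 by camera with the preset correlation and 0.0414 with an estimated one), and that value had been set beforehand as one that would exclude this explanation, but the bound was too weak, because the G1/S list had a lower median (-0.91 against -0.43) and the lists hold only part of the genes transcribed with the cycle. A loss of NFKB2 itself, or an off-target change of some regulator, may also contribute, and neither was tested.

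Genes that fell in each knockdown may partly reflect seed matches of the siRNA used. Of 14 7-mers that passed as linked to lower values in siNFKB2, 9 occur in NFKB2 transcripts. Of 10 in siRELB, 5 occur in RELB transcripts. In siNFKB2 the 7-mer most strongly linked to lower values was CAGCCAA (t = -12.63, log2 -0.223 in 1778 UTRs), which occurs in NFKB2 transcripts, as do 17.8% of all 7-mers, and had t = -0.36 in siRELB. In siRELB it was ACAAGAA (t = -14.49, log2 -0.143), which occurs in RELB transcripts, as do 11.9% of all 7-mers, and had t = -0.28 in siNFKB2. Of all genes searched, 37.8% carry at least 1 of the 4 such 7-mers of siNFKB2, among them EFEMP1, TXNIP, HADHA and BLM, which fell, and PRR9, IL1RL1 and CXCL8, which rose. Carriers made up 48.8% of genes called lower, 33.4% of those called higher and 36.4% of those not called. In siRELB 27.8% of all genes searched carry at least 1 of 2, among them CNDP2, ITGA2 and SCML1, which fell, and OLR1, TMEM255A and DCLK1, which rose. There the shares were 59.4% of genes called lower, 20.6% of those called higher and 27.6% of those not called. The 7-mers were picked from these same fold changes, so the shares are not separate support. Carrying one does not show that a given gene was lowered by it.

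Genes with ATTACAA in the 3′ UTR were higher in both knockdowns (t = 7.04 and 7.73), and in siNFKB2 against siRELB the link had t = 2.55 (unadjusted p = 0.0107 over 12412 genes) and did not pass Bonferroni adjustment over all 7-mers. A candidate explanation is that the non-silencing siRNA lowers such genes in siNS, which would raise them in both comparisons. Both comparisons use the same siNS libraries. Any other deviation of those libraries tied to 3′ UTR sequence would give the same pattern, and these values cannot tell them apart. As for the other 7-mers, t treats genes as replicates and does not measure the spread between libraries.

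Splits of the same 6 libraries numbered 10 per comparison, the real one included, too few for a share under 0.05. The real calls were 3869, 299 and 3934 in siNFKB2 against siNS, siRELB against siNS and siNFKB2 against siRELB, each reached by 1 of 10 splits, and the highest of the others was 0 each time. For lists called by camera the real numbers were 13, 6 and 10 and the highest of the others 11, 5 and 11, with 1, 1 and 3 of 10 splits as high, so other splits of these libraries also gave many lists. In siNFKB2 against siRELB the other splits that part 3 pairs of replicate numbers gave 8 lists each. For any difference among the 3 groups, 1 of 100 splits drawn from 280, the real one, gave as many as the real 4443 calls. That share is under 0.05, which argues against chance for this count if the libraries are independent, and the labels do not establish that. The 100 splits were drawn without regard to replicate numbers. Of the 47 that part the same-numbered siNFKB2 and siRELB libraries 1, the real one, gave as many, and so did 1 of all 36 splits that put each replicate number once in each group. The highest other split in each of these counts, 2544, kept the 3 siNFKB2 libraries together and mixed siNS with siRELB. The count among 3 groups thus rests largely on siNFKB2 and says little of chance in siRELB against siNS.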
